A study of Mus musculus with 7 samples.

How the data were processed

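RNA from GFP-high cells of the mouse intestine, isolated with Trizol, was measured on 7 dual-colour arrays: 2 replicates each of Dll1 cells at CD24 high, CD24 medium and CD24 low, and 1 sample of Lgr5 cells. Per the labels' protocols, 100 ng of total RNA was amplified and labelled with Agilent's low RNA input linear amplification kit, the sample carried Cy3 and whole small intestine RNA carried Cy5 on each array. Since the dyes were never exchanged, a dye effect cannot be separated from a difference to the reference, but it cancels between groups. Each array held 45018 spots, 43379 of them for genes and 1639 controls, with 41174 different gene probes of 60 nucleotides.

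Per the file headers, the array files hold spot and background intensity of both channels, extracted with Agilent Feature Extraction 10.5.1.1, and a ratio column in log10 units of Cy5 over Cy3. The deposited series matrix holds log10 ratios too. Checked spot by spot, it equals the ratio column with its sign turned, with a largest difference of 5e-06, so it gives sample over reference. Its columns have a median of 0, except −0.003049 for CD24 high replicate 2, as Agilent's dye normalisation centres each array. Nothing in these values gives an absolute amount of RNA.

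Mean spot signals were background corrected with normexp and an offset of 50, and log2 ratios were normalised within each array by loess with a span of 0.3, in limma 3.58.1 with data.table (version 1.17.8) under R 4.3.3. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No scaling between arrays was applied. Control spots carried no weight in the loess curve, and sample-channel outlier spots were left out. Probes were kept where the sample channel stood well above background on at least 2 of 7 arrays, which left 24495 probes. For each gene symbol the brightest probe was taken, which gave 17537 genes, 17319 of them with a value on all arrays, and 17481 in comparisons with Lgr5. Of all probes 26918 were named through a RefSeq accession and 14256 kept the name in the array file. Coordinates are those of the array files on mm9, and the RefSeq annotation used here is of another build, so it served for names alone.

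The median sample-channel intensity was 77.6 to 107.5 and that of the reference channel 300.3 to 325.7, with 0 saturated spots. Reference signal stood well above background on 73.9 to 78.6% of spots. Genes dim in a group have ratios held near a floor by the offset, so no fold is given against such a group. A gene's further probes mostly gave smaller differences than its brightest.

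Groups were taken from the sample labels. A linear model with 1 mean per group was fitted to all 7 arrays at once, so that the groups share an estimate of the spread, with 3 residual degrees of freedom and 3.55 prior degrees of freedom from limma's empirical Bayes step. The comparisons were CD24 medium against CD24 high, CD24 low against CD24 high, CD24 low against CD24 medium, the mean of the 3 Dll1 groups against Lgr5, and each Dll1 group against Lgr5. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Genes highest or lowest in a level passed in both comparisons of that level in the same direction. For 17 gene lists of 333 members, fixed from general knowledge before the data were examined, 310 entries were measured, and 7 symbols stand in 2 lists. They were tested with limma's camera at a preset correlation between genes of 0.01, with the correlation estimated from the data as an alternative. Tested on simulated data with 200 changed genes, the comparisons recovered 37 to 41 of 100 genes changed by 1 on the log2 scale and 98 to 100 of 100 changed by 2, and called 6 to 15 unchanged genes.

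Genes named in the text follow a rule set in advance. For each comparison between CD24 levels and for the Dll1 mean against Lgr5, they are the 10 largest positive and 10 largest negative differences among genes past the threshold whose replicate values do not overlap, or, for Lgr5, whose value lies outside the range of the 6 Dll1 arrays. Symbols of clones, predicted genes and accessions were passed over. To these come up to 4 members of each list with the largest absolute difference past the threshold, or up to 2 where none passed, the 10 genes with the largest smaller difference among those highest in 1 level, and always Cd24a, Dll1, Lgr5 and Atoh1. Separate comparisons with Lgr5 were to give list results alone. Any other gene is said to be chosen after its values were seen.

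The alternatives were no background subtraction, an offset of 16, Agilent's processed signals, quantile scaling of average intensity, the sample channel alone with quantile scaling, the series matrix, no filter on dim probes, a filter on all 7 arrays, the mean of all probes, slide as a term or a random block, the replicate number as a block, a fit of the compared groups alone, an intensity trend in the empirical Bayes step, a minimum difference of 1, the estimated correlation and leaving out each array. Added after the data were seen were slide 2 alone, leaving out probes that hold GTGCCC or GCCGCC, and the rank form of camera without a block. Results of some single genes that the rule names are not reported.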

Results

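Gene expression was measured on 7 dual-colour Agilent whole mouse genome arrays in cells sorted from the mouse intestine. Of these samples, 6 came from mice that carry green fluorescent protein (GFP) under the promoter of Dll1, a Notch ligand made by cells entering the secretory lineage. Their GFP-high cells were separated into CD24 low, CD24 medium and CD24 high by CD24, a surface protein encoded by Cd24a, with 2 samples per level. The remaining sample held GFP-high cells of mice that carry GFP under the promoter of Lgr5, a receptor of the Wnt pathway found on crypt base stem cells. Each sample carried Cy3 and was hybridised against Cy5-labelled RNA of whole small intestine. Levels are therefore log2 of sample over reference, given as mean ± SD with n = 2 per CD24 level and n = 1 for Lgr5. The comparisons ask how Dll1 cells at 3 CD24 levels differ from each other and from Lgr5 stem cells. The series calls its replicates biological without tying them to animals, so limma p-values of single genes measure the spread between these samples. None of that spread comes from Lgr5 samples, as there is 1 Lgr5 array. The small number of arrays limits the precision.

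Sample-channel signal stood well above background on 42.5 to 44.4% of gene spots on the CD24 high arrays and on 52.8 to 60.5% on the other arrays. Replicate arrays correlated at r = 0.90 to 0.94 across genes, which are not independent replicates, and the lowest r of any pair was 0.32. Slide 1 held the Lgr5 array with replicate 1 of CD24 high and of CD24 medium, and slide 2 held the other 4 arrays, so CD24 low was on slide 2 alone. Arrays are called high 1, medium 2 and so on by CD24 level and replicate. Below, a list median is the median log2 difference of the measured members, and a list's adjusted p comes from limma's camera test.

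Cd24a followed the CD24 gates, whereas Dll1 in CD24 high lay below its level in the Lgr5 array. Cd24a (probe at chromosome 10, 43303706 to 43303765, mm9) stood at 3.34 and 3.47 in the CD24 high replicates, at 0.88 and 0.75 in CD24 medium, at −0.68 and −0.59 in CD24 low and at −0.11 in Lgr5. Dll1 (chromosome 17, 15504623 to 15504682) stood at 2.81 and 2.53 in CD24 medium, at 2.56 and 2.52 in CD24 low, at 0.61 and −0.04 in CD24 high and at 0.88 in Lgr5. Lgr5 (chromosome 10, 114888847 to 114888906) was 2.51 in the Lgr5 array, 1.36 and 1.31 in CD24 high, −0.66 and −0.54 in CD24 medium and −1.23 and −0.75 in CD24 low. Atoh1, the transcription factor that commits crypt cells to secretory fates, stood at −1.08 in Lgr5, at 0.98 and 0.31 in CD24 high, at 1.21 and 0.37 in CD24 medium and at 1.67 and 1.67 in CD24 low. A gene used to choose the cells is no finding between them, which covers Cd24a between CD24 levels and Dll1 and Lgr5 between the mouse lines.

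**Figure D1:**
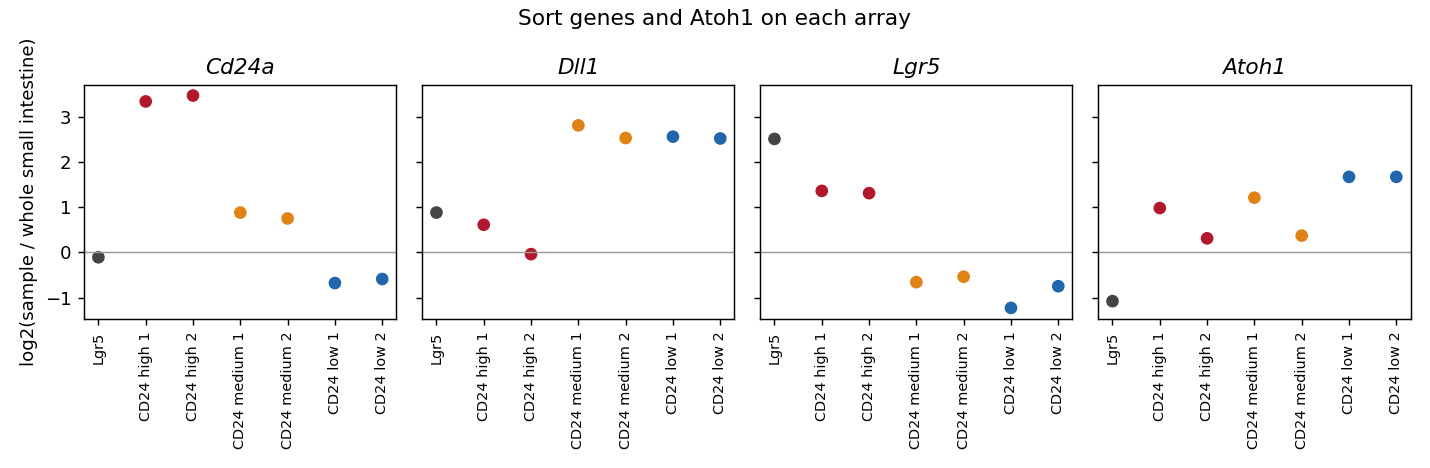
Log2 of sample over whole small intestine reference for Cd24a, Dll1, Lgr5 and Atoh1, with 1 point per array and the groups along the horizontal axis. Cd24a falls from 3.34 and 3.47 in CD24 high to −0.68 and −0.59 in CD24 low, while Lgr5 is 2.51 in the Lgr5 array and 1.36 and 1.31 in CD24 high.

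Between CD24 medium and CD24 high, Paneth and enteroendocrine genes moved in opposite directions. Of 21 Paneth genes, 20 were lower in CD24 medium, 0 were higher and 1, Defa-rs2, did not pass (20 lower adjusted over the list alone). Their median was −5.50 (−2.60 with the sample channel alone), with adjusted p = 2.7e-21 and adjusted p = 0.03 with an estimated correlation. Lyz1, the lysozyme of Paneth granules (chromosome 10, 116725254 to 116725313), stood at 6.20 ± 0.04 in CD24 high and −0.26 ± 0.34 in CD24 medium, 88.1-fold lower (log2 SE 0.28, adjusted p = 7.6e-05). Ang4, an antimicrobial angiogenin, was 76-fold lower (SE 0.49, adjusted p = 0.00065) and the alpha-defensins Defa21 and Defa4 were 350-fold and 181-fold lower. Alpha-defensin genes are near-identical, so the value of any single one is uncertain. Of 33 enteroendocrine genes, 25 were higher in CD24 medium, 1 was lower and 7 did not pass (28 higher and 1 lower adjusted over the list alone). The median was 2.92, with adjusted p = 6e-12 and adjusted p = 0.43 with an estimated correlation. Chgb, a chromogranin of hormone granules (chromosome 2, 132620703 to 132620762), stood at 4.55 ± 1.31 in CD24 medium and −0.60 ± 0.56 in CD24 high, 35.6-fold higher (SE 0.78, adjusted p = 0.007). Transcription factors of endocrine differentiation were higher too: Neurog3 24.1-fold (SE 0.75, adjusted p = 0.0092), and Pax4 and Rfx6 (adjusted p = 0.0053 and 0.0026), whose size is left open as CD24 high was not well above background on every array. Neurog3 lost its call without high 2 (adjusted p = 0.055) and on slide 2 alone (adjusted p = 0.055). Within slides 1 and 2 the Paneth medians were −5.52 and −5.39 and the enteroendocrine medians 2.15 and 3.65. The 1 lower enteroendocrine gene, Sst, which encodes somatostatin, was 3.04-fold lower (adjusted p = 0.02). It was chosen after its value was seen, and its call ended without high 1, medium 1 or high 2.

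Cell cycle genes were higher in CD24 medium than in CD24 high. Of 25 G2/M genes, 15 were higher, 0 were lower and 10 did not pass (16 and 1 adjusted over the list alone). The median was 0.74 (0.95 and 0.68 within slides 1 and 2, 2.14 with Agilent's processed signals and 1.32 with the sample channel alone), with adjusted p = 1.4e-06 and adjusted p = 0.12 with an estimated correlation. Cdc20, which activates the anaphase-promoting complex, was 4.91-fold higher (SE 0.25, adjusted p = 0.0024), and the proliferation marker Mki67 4.12-fold (SE 0.26, adjusted p = 0.004). Of 24 G1/S genes, 13 were higher, 1 was lower and 10 did not pass (13 and 2 adjusted over the list alone). Their median was 0.90 (0.91 and 0.84 within slides, 1.64 with processed signals), with adjusted p = 4.8e-05 and adjusted p = 0.43 with an estimated correlation. Uhrf1, which maintains DNA methylation at replication forks, was 3.26-fold higher (adjusted p = 0.011, and 0.064 without high 2). Stem cell and Wnt target genes share 5 members. Of 22 stem cell genes, 9 were lower, 1 higher and 12 did not pass (11 and 2 adjusted over the list alone). Their median was −0.70 (−0.66 and −0.70 within slides, −0.29 with processed signals and −0.22 with the sample channel alone), with adjusted p = 0.0025 and adjusted p = 0.18 with an estimated correlation. Lgr5 itself was 3.81-fold lower (SE 0.2, adjusted p = 0.0019) and Tnfrsf19, a receptor of crypt base cells, 3.27-fold (SE 0.2, adjusted p = 0.0031). Of 16 Wnt targets, 10 were lower, 1 higher and 5 did not pass (11 and 2 adjusted over the list alone). The median was −1.07 (−1.10 and −0.99 within slides, −0.47 with the sample channel alone), with adjusted p = 0.00034 and adjusted p = 0.15 with an estimated correlation. Nkd1, a feedback inhibitor of Wnt signalling, was 10.9-fold lower (SE 0.17, adjusted p = 0.00013), with −1.26 from a further probe against −3.45. Of 12 secretory commitment genes, 4 were higher, 1 lower and 7 did not pass (5 and 1 adjusted over the list alone). The median was 0.70 (0.40 and 0.93 within slides), with adjusted p = 0.043 and adjusted p = 0.55 with an estimated correlation. The 4 were Dll1, 5.25-fold (adjusted p = 0.0018), Sox4, 7.4-fold (0.0085, and 0.051 without high 2), Mfng, 4.73-fold (0.027, with a value on 1 of the 2 CD24 high arrays), and Neurog3. Of 11 Notch-receiving genes, Lfng was higher, Notch2, Hes1 and Heyl were lower and 7 did not pass (1 and 3 adjusted over the list alone), and the median of −0.18 (adjusted p = 0.41) turned to 0.78 with processed signals and 0.28 with the sample channel alone. Of 4 reserve stem cell genes 0 passed (0 adjusted over the list alone), with a median of −0.25 (adjusted p = 0.35), Lrig1 at −0.47 and Hopx at −0.34. Notch2 was not well above background on every CD24 high array, the group called higher, so its call is weak, nor was Heyl on every CD24 medium array. Calls of Lfng, Notch2, Hes1 and Heyl ended without high 2, medium 1 or medium 2. Those of Hes1 and Heyl also ended without high 1, and that of Hes1 without low 1 or low 2.

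Among the other mature lineages, goblet genes were divided between CD24 medium and CD24 high. Of 21 goblet genes, 9 were higher in CD24 medium, 4 lower and 8 did not pass (10 and 4 adjusted over the list alone). Their median of −0.11 and mean of 0.67 differed in sign, the test leaned upwards without passing (adjusted p = 0.21), and the median turned to 0.24 with the sample channel alone. Fcgbp, a mucus protein, was higher by 3.39 on the log2 scale (SE 0.27, adjusted p = 0.00065) and Bcas1 4.29-fold (SE 0.25, adjusted p = 0.0031). Zg16, a lectin of mucus granules, was 13.1-fold higher (adjusted p = 0.011, and 0.053 without medium 1 or 0.061 without high 2). Of 28 enterocyte genes, 8 were lower, 2 higher and 18 did not pass (12 and 3 adjusted over the list alone). Their median was −0.67 (−0.64 and −0.65 within slides, −0.37 with processed signals and −0.22 with the sample channel alone), with adjusted p = 0.0045 and adjusted p = 0.5 with an estimated correlation. Reg3g, an antimicrobial lectin, was 9.14-fold lower (SE 0.46, adjusted p = 0.0061), while the 2 higher genes were the keratin Krt20, 6.66-fold (SE 0.33, adjusted p = 0.0033), and Fabp2, 3-fold. Of 17 tuft genes, Gng13 was higher, 5 were lower, among them Ptgs1, Alox5, Alox5ap and Fyb, and 11 did not pass (1 and 6 adjusted over the list alone), with a median of −0.35 (adjusted p = 0.26). Genes of protein folding and secretory load were lower in CD24 medium for 7 of 23 members, with 0 higher and 16 that did not pass (9 lower adjusted over the list alone), a median of −0.79 (−0.80 and −0.84 within slides, −0.44 without high 1) and adjusted p = 0.00046, and adjusted p = 0.55 with an estimated correlation. Dnajc3 and Herpud1, both induced by stress of the endoplasmic reticulum, were 5.13-fold and 4.64-fold lower (adjusted p = 0.0062 and 0.0063). Immediate-early and stress genes were lower for 4 of 16 members, Jun, Atf3, Zfp36 and Nr4a1, with 12 that did not pass (7 lower adjusted over the list alone), a median of −0.87 (−1.37 and −0.33 within slides) and adjusted p = 0.043, and adjusted p = 0.55 with an estimated correlation. Jun was 3.69-fold lower (adjusted p = 0.019, and 0.096 without medium 2). Alox5ap and Fyb were chosen after their values were seen. Calls also ended without high 1 (Fabp2 0.073, Atf3 0.079, Nr4a1 0.1), without high 2 (Fabp2 0.099, Gng13 0.089, Ptgs1 0.17, Alox5 0.054, Alox5ap 0.14, Fyb 0.16, Atf3 0.057, Zfp36 0.05, Nr4a1 0.06), without medium 1 (Fabp2 0.11, Ptgs1 0.16, Alox5 0.087, Alox5ap 0.16, Fyb 0.16, Atf3 0.078, Zfp36 0.099, Nr4a1 0.1), without medium 2 (Ptgs1 0.14, Alox5 0.056, Alox5ap 0.14, Fyb 0.18, Atf3 0.082, Zfp36 0.12, Nr4a1 0.095), without low 1 (Alox5ap 0.051, Fyb 0.055) and without low 2 (Alox5ap 0.051, Fyb 0.055), and Zfp36, with a value on 1 CD24 high array, turned to 0.01 with the mean of all probes.

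Immune and mesenchyme markers passed between CD24 medium and CD24 high here, but their differences nearly vanished under other scalings. Of 20 immune genes, 9 were lower in CD24 medium and 11 did not pass (12 lower adjusted over the list alone). Their median was −0.78 (−0.63 and −0.88 within slides, −0.19 with processed signals and −0.07 with the sample channel alone), with adjusted p = 3e-04 and adjusted p = 0.43 with an estimated correlation. Cd52, a lymphocyte surface protein, was 2.2-fold lower (adjusted p = 0.0051). Of 14 genes of mesenchyme, endothelium and muscle, 8 were lower, Vim was higher and 5 did not pass (8 and 1 adjusted over the list alone). The median was −0.88 (−0.77 and −0.93 within slides, −0.05 and −0.03 under the same scalings), with adjusted p = 0.0018 and adjusted p = 0.44 with an estimated correlation. Tagln, an actin-binding protein of smooth muscle, was 2.41-fold lower (adjusted p = 0.0061). Of 3 erythroid genes, Hbb-bt and Hba-a1 were lower and 1 did not pass (3 lower adjusted over the list alone). The median was −0.87 (−0.66 and −1.08 within slides, −0.21 with the sample channel alone), with adjusted p = 0.028 and adjusted p = 0.43 with an estimated correlation. With processed signals the secretory commitment (0.41), enterocyte (0.051), immune (0.079), mesenchyme (0.2) and erythroid (0.16) lists did not pass. With the sample channel alone these 5 did not pass (0.16, 0.17, 0.13, 0.18 and 0.17), nor did the stem cell (0.051) and immediate-early (0.051) lists, the latter also not on slide 2 alone (0.5). Leaving out 1 array ended the calls of the secretory commitment list (without medium 1, 0.15, or high 2, 0.075), the enterocyte list (without medium 1, 0.06), the erythroid list (without high 2, 0.055) and the immediate-early list (without high 1, 0.67, or medium 2, 0.1, with its median at −0.04 without high 1 and −1.5 without high 2), and it brought the goblet list past the threshold without medium 2 (0.024). Of 20 immune members 14 and 12 stood well above background on the CD24 high arrays against 19 and 19 on CD24 medium, and of 14 mesenchyme members 11 and 10 against 14 and 13, so dim spots enter the group called higher. Single calls ended without high 1 (Vim 0.13), without high 2 (Vim 0.094, Hba-a1 0.1), without medium 1 (Hbb-bt 0.064, Hba-a1 0.13) and without medium 2 (Vim 0.13, Hba-a1 0.11). These are adjusted p-values.

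In all, 3654 of 17537 genes differed between CD24 medium and CD24 high by limma at an adjusted p under 0.05, 1319 higher and 2335 lower in CD24 medium. Outside the lists, Prm1, a sperm chromatin protein, Krtap19-1, a hair keratin-associated protein, Gp1bb, a platelet receptor subunit, and Ankrd9 were 285-fold, 185-fold, 139-fold and 107-fold lower, but a further probe of Prm1 gave −0.55, of Krtap19-1 0.24 and of Ankrd9 0.08. Scin, which severs actin filaments, was 28-fold higher (adjusted p = 0.0013). Several list members of the opposite direction were named after their values were seen: Prom1 2.27-fold, Cd44 1.8-fold and, lower, Dll3 2.77-fold, Pcna 1.68-fold, Spink4 3.85-fold, Qsox1 2.56-fold, Creb3l4 1.7-fold and Muc13 1.67-fold. The 2 further probes of Cd44 gave −0.52 and −0.05 against 0.85. Of these genes, Spink4 and Qsox1 kept their calls in every leave-out, although Spink4 turned to 0.24 with the sample channel alone. The others all lost theirs without medium 2. Prom1, Cd44, Dll3 and Creb3l4 also did without high 1, and Prom1, Cd44, Pcna, Creb3l4 and Muc13 without high 2. Cd44, Dll3, Pcna, Creb3l4 and Muc13 did without medium 1, and Dll3 without low 1 or low 2. processed signals gave 2983 higher and 2199 lower and the sample channel alone 2231 and 1903, with medians of all genes of 0.21 and 0.09 against 0.01. The count was 3614 with slide as a term and 1003 on slide 2 alone, a setting chosen after seeing the data. It was 1492 without medium 1, 1840 without high 2 and 1259 without medium 2, where a lone array is assumed to vary like the other groups.

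After the calls were seen, short sequences in the 60-nucleotide probes were counted. Probes holding GTGCCC were lower in CD24 medium by 2-fold or more for 98 of 196 genes and probes holding GCCGCC for 34 of 71, a 6.14-fold and a 5.88-fold excess (adjusted p = 8e-51 and 1.3e-15 over 3753 hexamers). The probes of Prm1, Krtap19-1 and Gp1bb hold GCCGCC and those of Ephb3 and Pcna hold GTGCCC. Without all such probes 1306 genes were higher and 2189 lower in CD24 medium.

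**Figure D2:**
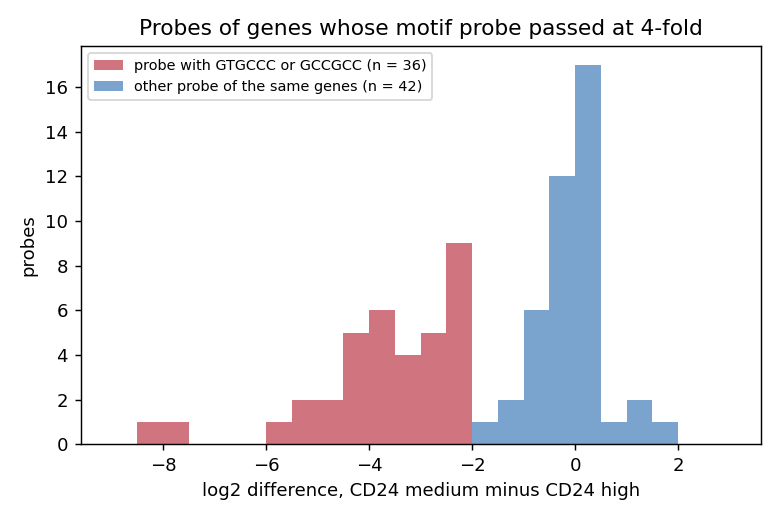
Histogram of log2 CD24 medium minus CD24 high for 36 probes that hold GTGCCC or GCCGCC and were lower by 4-fold or more, and for the 42 other probes of the same genes, with the number of probes on the vertical axis. The median is −3.51 for the first kind and −0.02 for the second.

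**Figure D3:**
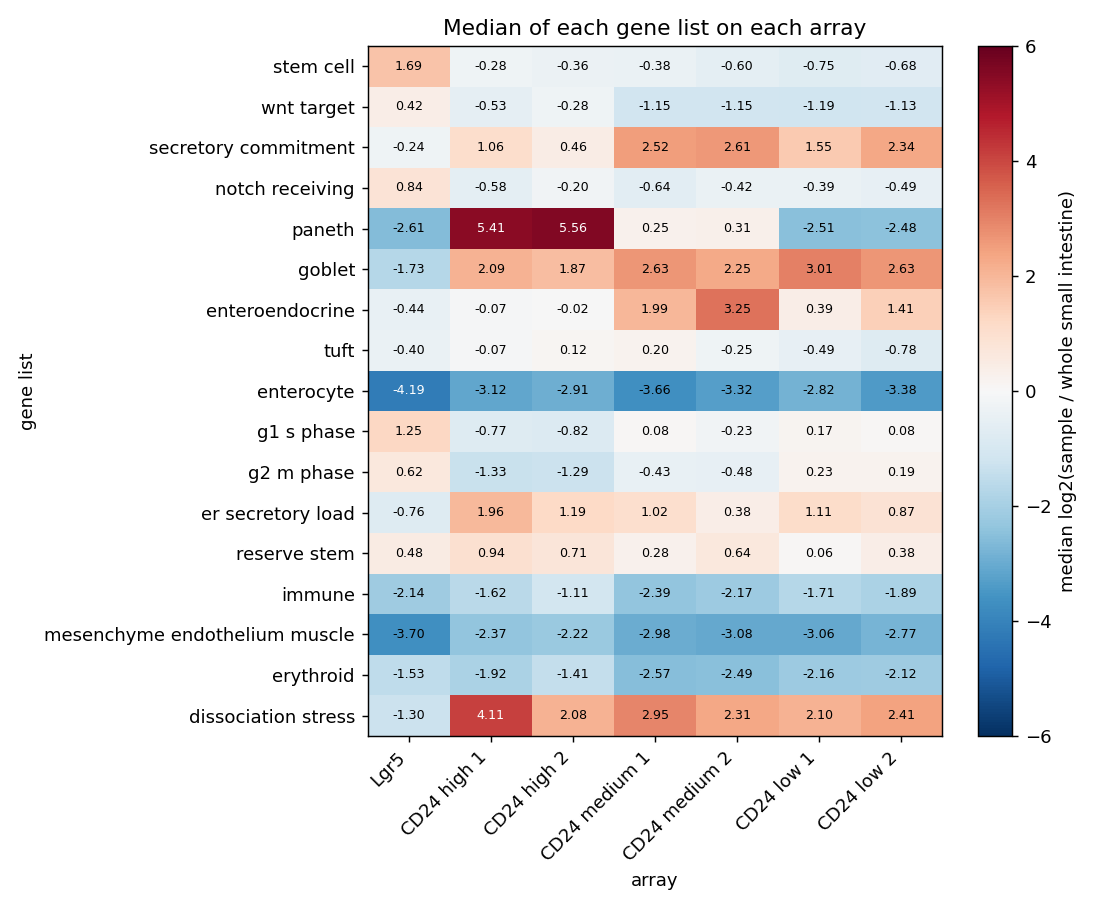
Median log2 of sample over reference of each of the 17 fixed gene lists on each of the 7 arrays, as a coloured grid with lists in lines and arrays in columns. The median difference of CD24 medium to CD24 high is −5.50 for Paneth genes and 2.92 for enteroendocrine genes, while the Notch-receiving median of −0.18 turns to 0.78 and 0.28 and the goblet median of −0.11 to 0.24 under other scalings.

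Between CD24 low and CD24 high, Paneth genes were again lower and cell cycle genes higher in CD24 low, and goblet genes were divided. Of 21 Paneth genes, 20 were lower and 1, Defa-rs2, did not pass (20 lower adjusted over the list alone). Their median was −7.91 (−8.02 with slide as a term and within slide 2, −5.4 with the sample channel alone). Adjusted p was 2.6e-26, and 0.022 with an estimated correlation. Lyz1 stood at −3.85 ± 0.51 in CD24 low, 1060-fold below CD24 high (SE 0.28, adjusted p = 1e-05), Itln1, a lectin of Paneth cells (chromosome 1, 173460678 to 173460736), was 626-fold lower (SE 0.15, adjusted p = 2.4e-06) and Defa4 1940-fold. Of 21 goblet genes, 10 were higher, 3 lower and 8 did not pass (10 and 4 adjusted over the list alone). Their median was 0.16 (0.31 with slide as a term, 0.16 within slide 2, 0.99 with the sample channel alone, 1.02 with the mean of all probes and 0.46 without low 2), with adjusted p = 0.018 and adjusted p = 0.57 with an estimated correlation. Clca1, a secreted mucus protein (chromosome 3, 144667558 to 144667617), was 101-fold higher (SE 1.23, adjusted p = 0.014), Zg16 45.2-fold (SE 0.63, adjusted p = 0.0025), and Fcgbp (chromosome 7, 28905517 to 28905576) stood at 3.40 ± 0.47 in CD24 low and −0.71 ± 0.31 in CD24 high, 17.3-fold higher (adjusted p = 0.00025). The goblet list did not pass without low 1 (0.06, adjusted p = 0.069) or with processed signals (0.14, adjusted p = 0.47). Of 33 enteroendocrine genes, 5 were higher, 2 lower and 26 did not pass (5 and 2 adjusted over the list alone). The median was 0.87 (0.61 with slide as a term, 0.84 within slide 2, 1.90 with processed signals and 1.53 without low 1), with adjusted p = 0.0045 and adjusted p = 0.57 with an estimated correlation. The median was 0.37 without low 2 (adjusted p = 0.069) and 0.57 with the sample channel alone (adjusted p = 0.17). Gip, the incretin made by K cells (chromosome 11, 95886745 to 95887966), was 16.6-fold lower (SE 0.28, adjusted p = 0.00029) and Sst 4.7-fold lower (adjusted p = 0.0065). Chga, Tac1 and Cck were 10.4-fold, 9.33-fold and 9.04-fold higher and Chgb and Tph1, which with Sst were chosen after their values were seen, 8.62-fold and 6.44-fold. Each of these 5 lost its call without high 1, high 2 or low 2 (adjusted p = 0.05 to 0.15), and Cck, Chgb and Tph1 with slide as a term (0.065 to 0.078).

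Of 25 G2/M genes, 19 were higher in CD24 low than in CD24 high and 6 did not pass (20 higher adjusted over the list alone). The median was 1.63 (1.60 with slide as a term, 1.55 within slide 2, 2.91 with processed signals), with adjusted p = 2.2e-14 and adjusted p = 0.036 with an estimated correlation. Cdc20 was 7.57-fold higher (SE 0.25, adjusted p = 0.00078) and Mki67 6.58-fold (SE 0.26, adjusted p = 0.0011). Of 24 G1/S genes, 14 were higher and 10 did not pass (17 and 1 adjusted over the list alone). Their median was 1.11 (1.19 and 1.16, 1.79 with processed signals), with adjusted p = 3.6e-07 and adjusted p = 0.44 with an estimated correlation, and Tk1, a thymidine kinase of S phase, was 3.88-fold higher (adjusted p = 0.0015). Of 22 stem cell genes, 8 were lower and 14 did not pass (9 and 1 adjusted over the list alone). Their median was −0.50 (−0.46 and −0.51, −0.23 with processed signals, −0.14 with the sample channel alone, −0.30 with the mean of all probes and −0.31 without low 1), with adjusted p = 0.0028 and adjusted p = 0.17 with an estimated correlation. Lgr5 was 5-fold lower (SE 0.2, adjusted p = 0.00077). Of 16 Wnt targets, 9 were lower and 7 did not pass (10 and 3 adjusted over the list alone). The median was −0.94 (−0.98 and −0.96, −0.55 with the sample channel alone), with adjusted p = 0.00099 and adjusted p = 0.16 with an estimated correlation, with Nkd1 12.5-fold lower (adjusted p = 6.4e-05, with −0.97 from a further probe against −3.65). Of 12 secretory commitment genes, Dll1 was 4.79-fold higher, Dll3 5.21-fold lower and 10 did not pass (5 and 1 adjusted over the list alone). This list's median was 0.55 (adjusted p = 0.11), and it passed with slide as a term (0.71, 0.028), on slide 2 alone (1.25, 0.016) and without high 1 (1.25, 0.034). Atoh1, at 1.02 (SE 0.33, adjusted p = 0.08), passed with slide as a term (1.4, 0.0072). Of 11 Notch-receiving genes 0 passed (0 adjusted over the list alone), and their median of −0.14 (adjusted p = 0.48) turned to 0.53 with processed signals and 0.16 with the sample channel alone. Of 4 reserve stem cell genes, Bmi1 was 1.81-fold lower (adjusted p = 0.037, and 0.069 to 0.13 without any Dll1 array but low 1) and 3 did not pass (3 lower adjusted over the list alone), with a median of −0.65 (adjusted p = 0.075, and 0.024 without low 2).

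Of 17 tuft genes, 7 were lower in CD24 low than in CD24 high and 10 did not pass (9 lower adjusted over the list alone). The median was −0.78 (−0.69 with slide as a term, −0.86 within slide 2, −1.62 with processed signals), with adjusted p = 0.0028 and adjusted p = 0.44 with an estimated correlation. Alox5ap, which activates 5-lipoxygenase, was 2.34-fold lower (adjusted p = 0.011, and 0.059 with the sample channel alone). Of 28 enterocyte genes, Krt20 (11.9-fold), Fabp2 (4.8-fold) and Dgat1 (1.61-fold) were higher, Reg3g (5.27-fold), Slc2a5 (3.22-fold) and Mgam (1.98-fold) lower and 22 did not pass (4 and 4 adjusted over the list alone). Their median of 0.01 and the downward test (adjusted p = 0.86) differed in sign, and Dgat1 and Mgam were chosen after their values were seen. A further probe of Mgam gave 0.26 against −0.99. Krt20, Fabp2 and Slc2a5 passed in every leave-out, while Reg3g did not without high 2 (0.06), Mgam without either CD24 high replicate or low 2 (0.05 to 0.058) and Dgat1 without any of the 6 Dll1 arrays (0.058 to 0.17). Of 23 genes of secretory load, 7 were lower and 16 did not pass (8 lower adjusted over the list alone). Their median was −0.42 (−0.25 with slide as a term, adjusted p = 0.1, and −0.21 within slide 2), with adjusted p = 0.0045 and adjusted p = 0.57 with an estimated correlation. Herpud1 was 5.46-fold lower (SE 0.32, adjusted p = 0.0042). Of 16 immediate-early and stress genes, Jun, Nr4a1, Atf3, Zfp36 and Junb were lower and 11 did not pass (8 lower adjusted over the list alone). Their median was −1.15 (−0.86 with slide as a term, −0.55 within slide 2), with adjusted p = 0.0062 and adjusted p = 0.57 with an estimated correlation. Jun was 7.11-fold and Nr4a1 4.89-fold lower (adjusted p = 0.0046 and 0.0053). Without high 1, the secretory load median was −0.21 (adjusted p = 0.12) and the stress median −0.55 (adjusted p = 0.093), and without high 2 they were −0.85 and −1.91, with −0.71 for secretory load without low 1. Of 20 immune genes, 3 were lower, among them Cd3d and Cd52, and 17 did not pass (3 lower adjusted over the list alone), and the median of −0.37 (adjusted p = 0.059) turned to 0.09 with processed signals and 0.05 with the sample channel alone. Of 14 mesenchyme, endothelium and muscle genes, Tagln, Col3a1 and Myh11 were lower and 11 did not pass (4 lower adjusted over the list alone), and the median of −0.44 (adjusted p = 0.059) turned to 0.09 with processed signals. Of 3 erythroid genes 0 passed (1 lower adjusted over the list alone), with a median of −0.50 (adjusted p = 0.076) and Hbb-bt at −0.73 (0.043 without high 1). Calls ended without high 1 (Atf3 0.057, Junb 0.061, Cd52 0.052, Tagln 0.058), without high 2 (Cd3d 0.16, Cd52 0.082, Tagln 0.069), without medium 1 (Junb 0.052, Cd3d 0.073), without medium 2 (Junb 0.052, Cd3d 0.073), without low 1 (Junb 0.086, Cd52 0.056) and without low 2 (Junb 0.078, Cd3d 0.17), and those of Col3a1 and Myh11 without any of the 6 Dll1 arrays (0.052 to 0.16). Junb was chosen after its value was seen. With slide as a term Zfp36, which has 1 CD24 high value and −0.48 from a further probe, did not pass (0.062), nor did Bmi1, Cd3d, Myh11, Dgat1 and Junb (0.054 to 0.081). The immune, mesenchyme and erythroid lists passed with slide as a term, at −0.50, −0.54 and −0.62 (adjusted p = 0.012, 0.019 and 0.047), and without high 1 (adjusted p = 0.0025, 0.0065 and 0.03).

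In all, 3164 genes differed between CD24 low and CD24 high by limma, 1200 higher and 1964 lower in CD24 low. Among the furthest apart outside the lists, Scin was 32.4-fold higher (adjusted p = 0.00095) and Lgals4, a galectin of the gut epithelium, 13.1-fold. The counts were 3308 higher and 2354 lower with processed signals, where the median of all genes was 0.23 against 0.02, and 2317 and 2124 with the sample channel alone. They were 2429 with slide as a term and 1321 on slide 2 alone, chosen after seeing the data, and 1927, 1898 and 1682 without high 1, high 2 or low 2.

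**Figure D4:**
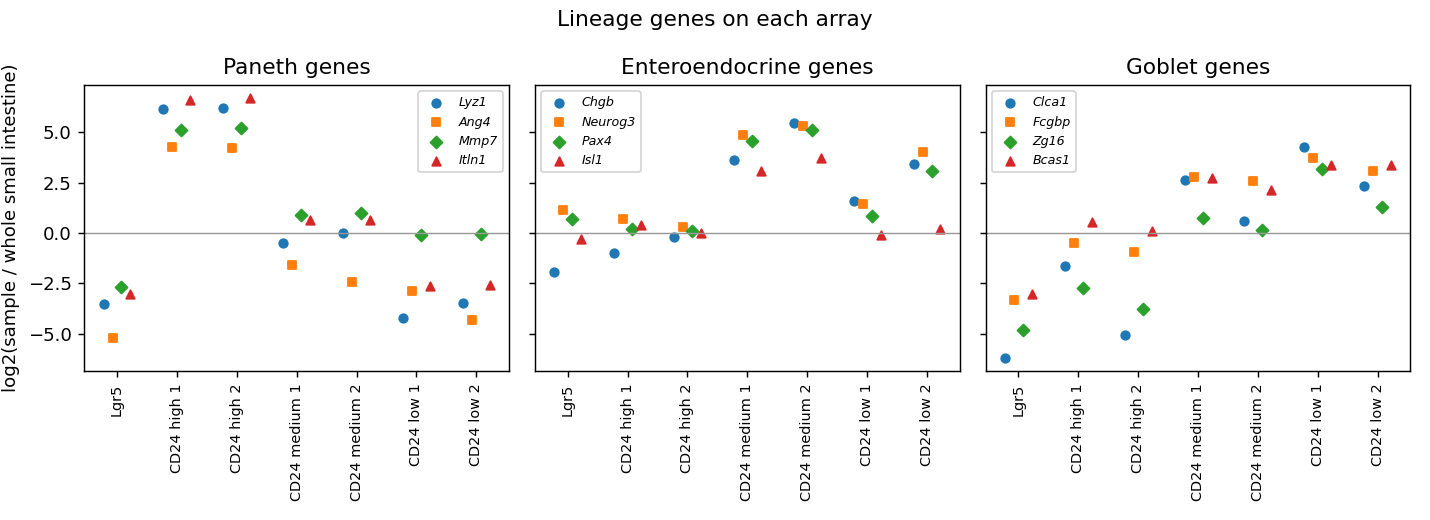
Log2 of sample over reference on each array for Paneth genes (Lyz1, Ang4, Mmp7, Itln1), enteroendocrine genes (Chgb, Neurog3, Pax4, Isl1) and goblet genes (Clca1, Fcgbp, Zg16, Bcas1), with 1 point per array. Lyz1 stands at 6.20 ± 0.04 in CD24 high and −3.85 ± 0.51 in CD24 low, Chgb at 4.55 ± 1.31 in CD24 medium and Fcgbp at 3.40 ± 0.47 in CD24 low.

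CD24 low and CD24 medium were closer, and the genes that passed singly, Paneth genes and the hormone gene Gip among them, were lower in CD24 low, while G2/M genes were higher as a set. Gip stood at 2.57 ± 0.10 in CD24 medium and −2.26 ± 0.46 in CD24 low, 28.3-fold lower (SE 0.28, adjusted p = 0.0034), and Itln1 at 0.64 ± 0.02 and −2.62 ± 0.04, 9.58-fold lower (SE 0.15, adjusted p = 0.0012). Of 21 Paneth genes, 8 were lower and 13 did not pass (17 lower adjusted over the list alone). The median was −2.23 (−2.36 with slide as a term, −2.37 within slide 2), with adjusted p = 5.3e-31 and adjusted p = 0.017 with an estimated correlation. Defa6 and Defa3 were 17.1-fold and 17.7-fold lower (adjusted p = 0.0012 each), and Lyz1 12-fold (adjusted p = 0.014, and 0.06, 0.06 and 0.081 without high 1, high 2 or medium 2). Of 33 enteroendocrine genes, Gip and Isl1 were lower and 31 did not pass (14 lower adjusted over the list alone). The median was −1.43 (−1.96 and −2.18, with −2.18, −0.90 and −0.72 without medium 1, low 1 or medium 2), with adjusted p = 1.3e-19 and adjusted p = 0.38 with an estimated correlation. Isl1, a transcription factor of endocrine cells (chromosome 13, 117088774 to 117088833), was 10.2-fold lower (SE 0.26, adjusted p = 0.014). It did not pass without high 1 (0.051), low 1 (0.084), high 2 (0.051) or medium 2 (0.053), nor with slide as a term (0.052). Neurog3 was at −2.37 (adjusted p = 0.37), and at −3.66 without low 2 (adjusted p = 0.02).

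No single gene of the remaining 15 lists passed over all genes between CD24 low and CD24 medium, but several lists moved as sets. G2/M genes were higher in CD24 low as a set (0 of 25 passed, 19 higher adjusted over the list alone). Their median was 0.66 (0.70 with slide as a term and within slide 2), with adjusted p = 2.1e-18 and adjusted p = 0.025 with an estimated correlation. Goblet genes had a median of 0.40 (0.51 and 0.52) and adjusted p = 4e-04, and adjusted p = 0.4 with an estimated correlation (0 of 21 passed, 0 adjusted over the list alone). Enterocyte genes had a median of 0.55 (0.45 and 0.46) and adjusted p = 7.7e-08, and adjusted p = 0.38 with an estimated correlation (0 of 28, 1 higher and 1 lower adjusted over the list alone), with Ada, adenosine deaminase, at 1.71 and at 2.78 without low 2 (adjusted p = 0.013). Tuft genes had a median of −0.30 (−0.31 and −0.18, with −0.92 from processed signals and −0.14 without low 2) and adjusted p = 0.00062, and adjusted p = 0.38 with an estimated correlation (0 of 17, 2 lower adjusted over the list alone), with Gng13, a G protein subunit of taste signalling, at −2.46 and at −2.96 without medium 2 (adjusted p = 0.038). G1/S genes had a median of 0.24 (0.37 and 0.44) and adjusted p = 0.0018, and adjusted p = 0.45 with an estimated correlation (0 of 24, 0 adjusted over the list alone). Immune genes had a median of 0.40 (0.33 and 0.40) and adjusted p = 2.3e-05, and adjusted p = 0.38 with an estimated correlation, and mesenchyme, endothelium and muscle genes 0.43 (0.30 and 0.34) and adjusted p = 4e-04, and adjusted p = 0.4 with an estimated correlation (0 of 20 and 0 of 14, 0 and 0 adjusted over the list alone). The sample channel alone ended the G1/S (0.052), immune (0.062) and mesenchyme (0.086) calls. The stem cell median of 0.06 and the Wnt target median of 0.11 stood against downward tests (adjusted p = 0.85 each) and turned to −0.19 and −0.18 with processed signals (0 of 22 and 0 of 16, 0 and 1 lower adjusted over the list alone). The secretory commitment (−0.31, adjusted p = 0.084), reserve stem cell (−0.24, 0.084), erythroid (0.39, 0.086), immediate-early (−0.34, 0.051) and secretory load (0.21, 0.22) lists did not pass, and nor did the Notch-receiving list (0.06, 0.73), whose median turned to −0.09 under the same scaling. Adjusted over the list alone, 1 gene was lower in each of the secretory commitment and reserve stem cell lists and 0 passed in the other 4.

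Leaving out 1 array at a time changed several of these lists between CD24 low and CD24 medium. Without low 1 or medium 2 the goblet (0.061 and 0.09) and G1/S (0.067 and 0.44) lists did not pass. The secretory load list passed without medium 1 (0.58, 3.3e-05) or low 2 (0.34, 0.0087) and turned to −0.15 without medium 2, and it passed with slide as a term (0.55, 4.5e-07). The immediate-early list passed without high 1 (0.0014), high 2 (0.00097), medium 2 (0.015) or low 2 (0.0087), but its median was 0.02 with slide as a term. The secretory commitment list passed without high 1 (0.036), high 2 (0.0061) or medium 2 (0.015), and the reserve stem cell list without medium 1 (0.044) or low 2 (0.02). By limma, 20 genes were lower in CD24 low and 0 higher, and at an unadjusted p under 0.05, 947 were lower and 919 higher. The count was 14 with slide as a term and 13 on slide 2 alone, 9 without high 1, high 2 or medium 2, 10 without low 1, 39 without medium 1 and 41 without low 2.

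Asked which level stood apart, CD24 high did. Its arrays differed too, with 23.9 to 24.9% of sample-channel signal in the top 20 probes, against 6.3 to 10.6% on the others. Agilent's Cy3 dye factor was 7.6 to 7.9, against 3.9 to 4.3. Their effect on the counts was not tested. In both comparisons 1654 genes were highest and 749 lowest in CD24 high, among them Defa21, Defa4 and Lyz1, 350-fold, 181-fold and 88.1-fold above the nearer of the other levels. Lowest in CD24 high were 2277 with processed signals and 1566 with the sample channel alone, so the balance of highest to lowest depends on the scaling. In CD24 medium 3 were highest and 0 lowest, and in CD24 low 0 were highest and 17 lowest. The 3 highest in CD24 medium were Isl1, which stood at 3.39 ± 0.45 against 0.19 ± 0.27 in CD24 high and 0.03 ± 0.21 in CD24 low, Ooep at 2.75 ± 0.42 and Lypd1 at 2.27 ± 0.13. Ooep and Lypd1 lost their calls between CD24 low and CD24 medium without high 1, high 2, low 1 or medium 2. Lypd1 also did without medium 1 or with slide as a term (0.085). Each level is shared by its 2 comparisons. Simulated groups with no changed gene gave 0.05 genes highest in CD24 high on average over 20 draws. With no changed gene the adjustment leaves almost no calls, so this is no baseline for the 1654. Independent lists would share 261.5, 90.3, 1.5 and 2.2 genes for highest and lowest in CD24 high, highest in CD24 medium and lowest in CD24 low. Part of the excess may come from the shared arrays, which are too few to split. The 1654 were 886, 855 and 1065 without medium 1, medium 2 or low 2, and 635 on slide 2 alone. The 749 were 443, 219, 212, 228 and 421 without high 1, medium 1, high 2, medium 2 or low 2, and 123 on slide 2 alone. The 3 were 0 without high 1, low 1 or high 2, 1 without medium 2, 26 without medium 1 and 15 without low 2. The 17 were 9, 10, 9 and 8 without high 1, low 1, high 2 or medium 2. Without low 2, 7 genes were lowest in CD24 medium and 9 highest in CD24 low.

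Against the Lgr5 array, the mean of the 3 Dll1 groups was higher in goblet, Paneth and secretory genes and lower in stem cell and cell cycle genes. The single Lgr5 array is assumed to vary like the Dll1 groups. Muc2, the main intestinal mucin (chromosome 7, 148940000 to 148940059), stood at −3.96 in Lgr5 and was 76.2-fold higher in the Dll1 mean (log2 6.25, SE 0.33, adjusted p = 0.00022, with 3.04 to 3.88 from further probes), and Agr2, needed for mucin folding, 54.7-fold (SE 0.25, adjusted p = 0.00016). Of 21 goblet genes, 20 were higher and 1 did not pass (21 adjusted over the list alone). Their median was 4.65 (4.80 with slide as a term, 4.48 within slide 1, which lacks CD24 low). The test gave adjusted p = 9.8e-16, and 0.13 with an estimated correlation. Of 21 Paneth genes, 20 were higher and 1 did not pass (20 adjusted over the list alone). The median was 3.96 (4.04, 6.21 without CD24 low and 2.73 with the sample channel alone). Adjusted p was 4e-14, and 0.032 with an estimated correlation. The protease Mmp7 was 25.8-fold higher (SE 0.16, adjusted p = 0.00015). Of 12 secretory commitment genes, 8 were higher, Dll1 of the sort among them, and 4 did not pass (9 adjusted over the list alone). The median was 1.63 (1.87 and 1.90), with adjusted p = 0.00079 and adjusted p = 0.27 with an estimated correlation. Spdef, a transcription factor of goblet and Paneth maturation, was 30.3-fold higher (SE 0.23, adjusted p = 0.00017), Gfi1, which acts downstream of Atoh1, 13.1-fold (SE 0.38, adjusted p = 0.0014) and Atoh1 4.33-fold (SE 0.36, adjusted p = 0.0071, and 0.1 with the sample channel alone). Of 33 enteroendocrine genes, 16 were higher and 17 did not pass (17 adjusted over the list alone). Their median was 1.92 (1.54 and 2.00), with adjusted p = 1.1e-05 and adjusted p = 0.4 with an estimated correlation, and Sct, which encodes secretin, was 33.8-fold higher (SE 0.29, adjusted p = 0.00028). Of 23 genes of secretory load, 19 were higher and 4 did not pass (20 adjusted over the list alone). Their median was 2.02 (2.27 and 2.30), with adjusted p = 4.1e-07 and adjusted p = 0.33 with an estimated correlation. Xbp1, a transcription factor of the unfolded protein response, was 5.67-fold higher (SE 0.26, adjusted p = 0.0014). Of 28 enterocyte genes, 16 were higher and 12 did not pass (17 adjusted over the list alone). The median was 1.04 (0.89 and 0.82, 0.48 with the sample channel alone), with adjusted p = 0.00012 and adjusted p = 0.27 with an estimated correlation, and Krt20 was 15-fold higher (adjusted p = 0.00099). Of 17 tuft genes, Avil, Ptgs1, Fyb and Alox5ap were higher and 13 did not pass (1 adjusted over the list alone). The median was 0.50 (0.59 and 0.72, 0.28 with the sample channel alone), with adjusted p = 0.025 and adjusted p = 0.35 with an estimated correlation. Avil, an actin-bundling protein of tuft cells, was 2.82-fold higher (adjusted p = 0.0052). The other 3 did not pass without medium 1 or medium 2, nor Fyb and Alox5ap without low 1 or low 2. With slide as a term Ptgs1, Fyb and Alox5ap did not pass (0.12, 0.14 and 0.14).

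Olfm4, a secreted marker of crypt base stem cells (chromosome 14, 80421398 to 80421457), stood at 3.04 in Lgr5 and was 19.4-fold lower in the Dll1 mean (SE 0.28, adjusted p = 0.00043), and the stem cell list gene Scn2b was 17.5-fold lower (SE 0.25, adjusted p = 0.00031). Of 22 stem cell genes, 18 were lower, Lgr5 of the sort among them, 1 was higher and 3 did not pass (19 and 1 adjusted over the list alone). Their median was −2 (−2.04 and −2.05), with adjusted p = 3.3e-13 and adjusted p = 0.032 with an estimated correlation. Of 24 G1/S genes, 22 were lower and 2 did not pass (22 adjusted over the list alone). Their median was −1.55 (−1.35 and −1.66), with adjusted p = 3.3e-13 and adjusted p = 0.17 with an estimated correlation. Rrm1, a ribonucleotide reductase subunit, was 4.44-fold lower (SE 0.19, adjusted p = 0.00099). Of 25 G2/M genes, 22 were lower and 3 did not pass (23 adjusted over the list alone). The median was −1.27 (−1.23 and −1.64), with adjusted p = 2.6e-12 and adjusted p = 0.032 with an estimated correlation, and the mitotic kinase Aurka was 3.78-fold lower (adjusted p = 0.0013). Of 16 Wnt targets, 8 were lower, again with Lgr5, 2 were higher and 6 did not pass (9 and 3 adjusted over the list alone). The median was −0.89 (−0.66 and −0.80, −1.34 with processed signals), with adjusted p = 0.00012 and adjusted p = 0.1 with an estimated correlation. Sp5, a transcription factor induced by Wnt, was 6.65-fold lower (adjusted p = 0.00049) and Myc 3.4-fold (adjusted p = 0.0014). Of 11 Notch-receiving genes, Dtx4, Notch2, Nrarp, Notch1 and Hes5 were lower, Heyl was higher and 5 did not pass (5 and 2 adjusted over the list alone). Their median was −0.64 (−0.76 and −0.62, turning to 0.08 with the filter on all 7 arrays, −1.71 with processed signals), with adjusted p = 0.0098 and adjusted p = 0.17 with an estimated correlation. Notch1, a Notch receptor, was 2.71-fold lower (adjusted p = 0.004), while a further probe of Notch2 gave 0.24 against −2.27. Of 4 reserve stem cell genes 0 passed (0 adjusted over the list alone), with a median of −0.10 (adjusted p = 0.5). The genes Msi1, Nkd1, Notum, Heyl and Hes5 were chosen after their values were seen. The first 3 were 1.54-fold, 1.77-fold and 1.81-fold higher in the Dll1 mean, as was Heyl over a dim Lgr5 spot, and these 4 did not pass with slide as a term (adjusted p = 0.091, 0.067, 0.09 and 0.052), and Hes5 was 2.13-fold lower (adjusted p = 0.0044). Msi1 did not pass without replicate 1 or 2 of CD24 high or CD24 medium (0.055 to 0.084), nor Notum without medium 1 (0.051) or medium 2 (0.054).

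Immediate-early and stress genes stood far above the Lgr5 array in the Dll1 groups. Of 16, 14 were higher and 2 did not pass (14 adjusted over the list alone). Their median was 3.30 (3.67 and 4.06), with adjusted p = 6.3e-06 and adjusted p = 0.27 with an estimated correlation. Nr4a1 was 65.5-fold, Atf3 56.4-fold and Egr1 28.3-fold higher (adjusted p = 0.00031, 0.00031 and 0.003). Of 20 immune genes, 7 were higher and 13 did not pass (10 and 1 adjusted over the list alone). The median was 0.75 (0.47 with slide as a term, adjusted p = 0.07, and 0.53 within slide 1), with adjusted p = 0.017 and adjusted p = 0.35 with an estimated correlation. Jchain, a joining chain of secreted antibodies, was 3.25-fold higher (adjusted p = 0.012, and 0.092 with the sample channel alone). Of 14 mesenchyme, endothelium and muscle genes, 9 were higher and 5 did not pass (12 adjusted over the list alone). The median was 0.88 (0.72 and 0.78), with adjusted p = 0.00021 and adjusted p = 0.27 with an estimated correlation, and Tagln was 2.51-fold higher (adjusted p = 0.0047). The sample channel alone ended the immune (0.08, adjusted p = 0.43) and mesenchyme (0.25, 0.11) calls and processed signals the immune call (0.31, 0.17). Of 3 erythroid genes, Hbb-bt was 4.43-fold lower (adjusted p = 0.0014) and 2 did not pass (2 lower adjusted over the list alone). Their median was −0.58 (−0.78 and −0.72, −1.82 with processed signals), with adjusted p = 0.02 and adjusted p = 0.27 with an estimated correlation. In all, 5389 of 17481 genes differed by limma, 3059 higher and 2330 lower in the Dll1 mean, and 3477 did with slide as a term. Sample channel values alone gave 2020 higher and 3034 lower. The median of all genes was 0.13.

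Taken 1 level at a time against Lgr5, Paneth genes separated the levels. They were higher for 20 of 21 genes in CD24 high and for 18 in CD24 medium (20 and 18 adjusted over the list alone). Their medians were 8.20 (5.53 with the sample channel alone) and 3.20. Adjusted p was 1.1e-17 and 1.1e-13, and 0.037 and 0.031 with an estimated correlation. In CD24 low 5 were higher and 1 lower (5 and 3 adjusted over the list alone, median 0.25, adjusted p = 0.25). Those were Mmp7, Pla2g2a, Nupr1, Ccl6 and Wnt3, from 2.77-fold to 35.4-fold higher, and Defa20, 1.85-fold lower, all chosen after their values were seen. Wnt3 did not pass with slide as a term (adjusted p = 0.082), and Defa20 did not pass without replicate 1 or 2 of CD24 high (0.056 each) or of CD24 medium (0.081 each), nor without low 1 (0.094) or with slide as a term (0.13). Goblet genes were higher for 18, 20 and 20 of 21 genes in CD24 high, CD24 medium and CD24 low (19, 21 and 21 adjusted over the list alone), with medians of 4.13 (2.74 with the sample channel alone), 4.73 and 4.74 (adjusted p = 3.1e-12, 3.3e-19 and 1.1e-18), and adjusted p = 0.23, 0.1 and 0.13 with an estimated correlation. Enteroendocrine genes were higher for 4, 23 and 8 of 33 genes (3, 29 and 12 adjusted over the list alone), with medians of 0.51, 3.94 and 1.46 (adjusted p = 0.2, 1.5e-12 and 0.00051), and adjusted p = 0.31 and 0.51 with an estimated correlation for the latter 2 levels. The 4 in CD24 high, chosen after their values were seen, were Sct, 24.5-fold higher, Gip, 12.7-fold, Ghrl, 7-fold (adjusted p = 0.032, and 0.11 without high 2), and Sst, 4.35-fold. The CD24 low call ended with slide as a term (0.84, adjusted p = 0.055). Stem cell genes were lower for 15, 18 and 18 of 22 genes (16, 20 and 21 adjusted over the list alone), with medians of −1.76, −2.14 and −2.35 (adjusted p = 1.2e-07, 1e-15 and 6.3e-15), and adjusted p = 0.057, 0.031 and 0.058 with an estimated correlation. G2/M genes were lower for 21, 18 and 6 of 25 (23, 21 and 8 adjusted over the list alone), with medians of −2.09 (−3.46 with processed signals), −1.11 and −0.50 (adjusted p = 3.7e-14, 2.6e-12 and 0.00011), and adjusted p = 0.037, 0.033 and 0.13 with an estimated correlation. G1/S genes were lower for 20, 20 and 16 of 24 (21, 22 and 21 adjusted over the list alone), with medians of −2.29, −1.34 and −1.13 (adjusted p = 1.5e-12, 2.9e-13 and 3.5e-10), and adjusted p = 0.23, 0.16 and 0.25 with an estimated correlation. Within slide 1, the CD24 high and CD24 medium medians were 8.95 and 3.20 for Paneth, 4.21 and 4.98 for goblet, 0.49 and 3.39 for enteroendocrine, −1.71 and −2.11 for stem cell, −2.11 and −1.17 for G2/M and −2.14 and −1.14 for G1/S genes. CD24 low and Lgr5 share no slide, so their comparison has no value within a slide.

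The other lists are given as medians against Lgr5 for CD24 high, CD24 medium and CD24 low in that order. Wnt targets had −0.69, −1.16 and −1.10 (adjusted p = 0.089, 1.9e-07 and 2.3e-07), and adjusted p = 0.044 and 0.085 with an estimated correlation for the latter 2. Secretory commitment genes had 1.14 (0.64 with the sample channel alone, 0.55 with the filter on all 7 arrays, where it did not pass), 2.28 and 1.62 (adjusted p = 0.046, 1.2e-05 and 0.00051), and adjusted p = 0.46, 0.22 and 0.28 with an estimated correlation. Notch-receiving genes had −0.67, −0.72 (0.07 with the filter on all 7 arrays, where none of the 3 passed) and −0.87, or −2.29, −1.15 and −1.69 with processed signals (adjusted p = 0.033, 0.0071 and 0.009), and adjusted p = 0.29, 0.16 and 0.23 with an estimated correlation. Genes of secretory load had 2.54, 1.62 and 1.80 (adjusted p = 3.7e-07, 6e-07 and 1e-06), and adjusted p = 0.33, 0.36 and 0.35 with an estimated correlation, and enterocyte genes 1.23, 0.56 and 1.13 (adjusted p = 0.00017, 0.0095 and 5.6e-06), or 0.30, 0.22 and 0.68 with the sample channel alone, where CD24 medium did not pass, and adjusted p = 0.32, 0.39 and 0.28 with an estimated correlation. Tuft genes had 0.82, 0.54 and 0.10, or 0.53, 0.23 and −0.10 with the sample channel alone (adjusted p = 0.0076, 0.021 and 0.5), and adjusted p = 0.32 and 0.36 with an estimated correlation for the first 2. Immediate-early genes had 4.41, 3.06 and 2.54 (adjusted p = 1.8e-05, 9e-07 and 6.7e-06), and adjusted p = 0.32, 0.27 and 0.28 with an estimated correlation. Immune genes had 1.13, 0.28 and 0.65 (adjusted p = 0.0037, 0.42 and 0.011), and adjusted p = 0.32 and 0.35 with an estimated correlation for the 2 that passed, neither of which passed with processed signals (0.17 and 0.058) or the sample channel alone (0.26 and 0.42, medians 0.09 and 0.06). Mesenchyme, endothelium and muscle genes had 1.33, 0.47 and 0.94 (adjusted p = 0.00013, 0.0095 and 0.00014), and adjusted p = 0.32, 0.39 and 0.28 with an estimated correlation, and did not pass with the sample channel alone (0.11, 0.32 and 0.071, medians 0.26, 0.09 and 0.25). Erythroid genes had −0.14, −1 and −0.61, or −1.71, −1.81 and −1.93 with processed signals (adjusted p = 0.21, 0.0049 and 0.015), and adjusted p = 0.22 and 0.28 with an estimated correlation for the latter 2, and reserve stem cell genes 0.25, −0.10 and −0.39 (adjusted p = 0.92, 0.55 and 0.22). Leaving out 1 array ended calls of secretory commitment (without high 1, low 1 or low 2) and Notch-receiving (without high 1) in CD24 high. It also ended those of tuft in CD24 medium (without medium 1) and immune in CD24 low (without low 1).

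By limma, 6266 genes differed between CD24 high and Lgr5 (3707 higher, 2559 lower), 3283 between CD24 medium and Lgr5 (1797 and 1486) and 3798 between CD24 low and Lgr5 (2088 and 1710). processed signals gave 3212 higher and 4005 lower for CD24 high, and the sample channel alone 2617 and 3668, 1247 and 1673, and 1413 and 2188. With slide as a term the counts were 5448, 2521 and 1402. For CD24 medium the count was 1838 and 1371 without medium 1 or medium 2, and for CD24 low 2302 without low 2. The root mean square log2 difference to the Lgr5 array was 1.23 ± 0 for CD24 high, 0.90 ± 0.05 for CD24 medium and 0.92 ± 0.06 for CD24 low, and within slide 1 it was 1.23 and 0.87 for CD24 high and CD24 medium. No test was made of these distances, since there is 1 Lgr5 array.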

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

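The test of handling, of the slide and of mixed-in stem cells, the test on other probes of the same genes and the 3 tests on probes outside the search for the sequences or on their genes were chosen after the result was seen. The control spots, which no comparison uses, gave a signal on every array. Spike-in signal over background in the sample channel was 18.53 and 22.06 in CD24 high replicates 1 and 2, 48.06 and 50.67 in CD24 medium, 46.87 and 37.12 in CD24 low and 56.58 in Lgr5. In the reference channel it was 95.9 to 101.7. No cause of the lower value in CD24 high was tested.

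Probes holding GTGCCC or GCCGCC read higher in CD24 high than in CD24 medium. Both sequences were found in these same calls, after a search over several fold thresholds, comparisons and directions. In 66 of 137 genes with probes of both kinds, the probe with the sequence was lower in CD24 medium than the other by over 1 on the log2 scale, and in 2 it was higher by as much, but these take in the probes searched. In 53 genes not used in the search, 22 were lower so and 0 higher (exact sign test over genes p = 4.8e-07), which argues against expression of those genes alone. Among probes not used in the search, all of genes whose brightest probe was not called, 15 of 55 with a sequence and 100 of 5317 without were lower by 2-fold or more (odds ratio 19.5). GC content is argued against as the whole source. Of these 55, 27.3% were lower so, against a mean of 1.98% and at most 10.9% in 1000 draws of probes of matched GC content. Among the probes searched the share was 49.4%, against a mean of 9.69% in matched draws. The ratios of 13.7 and 5.1 are not comparable, since leaving out genes with a called brightest probe lowers the matched share. A signal that follows the probe sequence is therefore a candidate explanation, whose source was not tested. For genes whose probe was lower by 4-fold or more, the median of their other probes was −0.02, but the control for this test, at −0.95, missed its bound of −1. Higher expression of the genes themselves thus stays open, also for genes measured by such a probe alone, Gp1bb among them.

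Immediate-early genes stood above the Lgr5 array on all 6 Dll1 arrays, with list medians of 5.09 and 3.38 for CD24 high replicates 1 and 2, 3.05 and 3.07 for CD24 medium and 2.23 and 2.84 for CD24 low. The slide or scan is argued against as the whole source by the lower of the 2 values within slide 1, 3.05. Handling of the single Lgr5 sort cannot be told apart from a difference between the cell types, since the lowest value of 2.23 is met by either and there is 1 Lgr5 array. A biological difference between Dll1 and Lgr5 cells also stays open and was not tested.

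Lgr5 mRNA stood above the reference in CD24 high, at 0.44 of its level in the Lgr5 array (log2 −1.18, SE 0.24). Stem cells of the Lgr5 kind mixed into that sort are argued against as the whole source. The 13 other stem cell genes at least 2-fold above the reference in the Lgr5 array had a median of −1.93 between CD24 high and Lgr5, 7 of them lay below Lgr5 itself by over 2 SE, and the 5 highest had a median of −3.78. Scn2b, Cdca7 and Olfm4 reached 0.059, 0.071 and 0.073 of the Lgr5 array, while Soat1 reached 0.88 and Smoc2 1.5. Those 2 rest on 1 probe each, as further probes gave log2 values of −2.77 to −0.69 and −0.82. Cross-hybridisation of the Lgr5 probe through the 2 sequences above is argued against, as 0 Lgr5 probes hold them, which says nothing of other sequences. Some Lgr5 expression in CD24 high cells remains open and was not otherwise tested.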

How the results depend on the processing

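Slide 2 alone, leaving out probes that hold GTGCCC or GCCGCC, and cameraPR without a block were chosen after the data were seen. Below, a count is of genes unless lists are named, and "high", "medium" and "low" stand for CD24 levels. Of called named genes, 45 of 86 kept their call in every leave-out for medium against high, 51 of 74 for low against high, 6 of 13 for low against medium, 69 of 78 for the Dll1 mean against Lgr5, and 8 of 9, 2 of 2 and 6 of 7 for high, medium and low against Lgr5. Of called lists, 9 of 13, 6 of 10, 7 of 9, 16 of 16, 11 of 13, 14 of 15 and 13 of 14 did so in that order. Under the other alternatives, gene values kept their call or lack of it 4755 times, lost it 295 times, gained it 23 times and reversed 3 times, and list values 1786, 169, 34 and 0 times. The 3 were Spink4 for medium against high (0.24, sample channel alone), Zfp36 for medium against high (0.01, mean of all probes) and Notch2 for the Dll1 mean against Lgr5 (0.24, filter on all 7 arrays). Spot signal over background limits the sample channel most in high, where 42.5 to 44.4% of spots stood well above it. Quantile scaling of average intensity moved no count of genes by over 1.5 times.

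Leaving out 1 array gave 1259 to 3979 genes for medium against high, 1682 to 3363 for low against high, 9 to 41 for low against medium, 4058 to 5768 for the Dll1 mean against Lgr5, and 4890 to 6356, 1371 to 3628 and 2302 to 3870 for high, medium and low against Lgr5. Genes highest in high numbered 855 to 1654, lowest in high 212 to 899, highest in medium 0 to 26, lowest in medium 0 to 7, highest in low 0 to 9 and lowest in low 8 to 17. Called lists numbered 11 to 13, 9 to 12, 7 to 12, 16, 11 to 13 and 14 to 15 in the order above. Low against Lgr5, with a list at the threshold, is left out. Fewer arrays leave fewer degrees of freedom.

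For the settings below the cause was not tested. No background subtraction gave 5035 genes for low against high, 34 for low against medium, 2500 highest in high, 9 highest in medium, 1 lowest in medium, 1 highest in low and a distance of high to Lgr5 of 1.27. An offset of 16 gave 12 for low against medium, 483 lowest in high, 10 lowest in low and distances of 1.34, 1.00 and 1.02 for high, medium and low. Agilent's processed signals gave 5662 for low against high, 2277 lowest in high, 1 lowest in medium, 1 highest in low, 8 lists for medium against high and distances of 1.76, 1.25 and 1.29, and the series matrix 5674, 2277, 1, 1, 8 and 1.76, 1.26 and 1.30. The sample channel alone gave 1566 lowest in high, 0 highest in medium, 6 lists for medium against high and distances of 1.1, 0.77 and 0.79. Without a filter on dim probes the distances were 0.98, 0.73 and 0.74, and with a filter on all 7 arrays 1.35, 0.97 and 1.00, with 1 highest in medium, 1 lowest in medium and 2 highest in low. The mean of all probes gave distances of 1.15 for high and 0.86 for medium. Slide as a term gave 3477 for the Dll1 mean against Lgr5, 1402 for low against Lgr5 and 11 lowest in low. Slide as a random block, tested with cameraPR, gave 6 lists for low against high, as did cameraPR without a block (6). An intensity trend gave 1 lowest in medium and 1 highest in low.

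Other settings use fewer samples or a stricter test by construction. A minimum difference of 1 gave 2027 for medium against high, 1824 for low against high, 3078 for the Dll1 mean against Lgr5, 1037 highest in high and 287 lowest in high. A fit of the compared groups alone gave 9 for low against medium and 2294 for low against Lgr5. Slide 2 alone gave 1003, 1321 and 13 for the 3 comparisons between levels, 635 highest and 123 lowest in high and 9 lowest in low. The estimated correlation left 1, 2, 2, 3, 2, 4 and 0 lists in the order above.

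The replicates of the CD24 levels share a number and no stated pairing, and their deviations from the group means correlated at 0.30 for high and medium, −0.005 for high and low and 0.477 for medium and low. With the replicate number as a block, 1503 genes were higher and 2513 lower for medium against high, 1452 and 2135 for low against high, 0 and 29 for low against medium, and 8 highest in medium.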

Other observations

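The genes below were chosen after their values were seen, except Gip between CD24 low and CD24 high. Hormone genes did not follow 1 order over the CD24 levels. Gip stood at 1.80 ± 0.38 in CD24 high, 2.57 ± 0.10 in CD24 medium and −2.26 ± 0.46 in CD24 low, with −1.87 in Lgr5. Sst stood at 0.72 ± 0.20, −0.89 ± 0.71 and −1.52 ± 0.22, with −1.40 in Lgr5. Chgb stood at −0.60 ± 0.56, 4.55 ± 1.31 and 2.51 ± 1.33. So Gip was 16.6-fold and Sst 4.7-fold lower in CD24 low than in CD24 high (adjusted p = 0.00029 and 0.0065), while Chgb was 8.62-fold higher (adjusted p = 0.039). The Chgb call ended without high 1 (0.15), high 2 (0.096) or low 2 (0.15).

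Some Wnt targets stood higher in CD24 high than in the Lgr5 array. Ephb3, a receptor that positions cells at the crypt base, stood at 3.84 ± 0.16 in CD24 high and 1.33 in Lgr5, 5.69-fold higher (SE 0.24, adjusted p = 0.00074), though its probe holds GTGCCC. The Wnt feedback inhibitors Nkd1 and Notum were 9.12-fold and 3.05-fold higher (adjusted p = 0.00021 and 0.0033), at −0.96 ± 0.06 and −0.96 ± 0.27 in CD24 high and −4.15 and −2.57 in Lgr5, so both stayed below the reference. A further probe of Nkd1 gave 1.61 against 3.19. The Wnt target list did not pass (−0.69, adjusted p = 0.089, 8 of 16 genes lower and 3 higher), but did without probes holding GTGCCC or GCCGCC (−0.94, 0.032).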
